A study of Rattus norvegicus with 2 samples.

How the data were processed

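Total RNA of ventral and lateral prostate was amplified with amino allyl labelling, coupled to Cy5 or Cy3 and hybridised to a two-colour oligonucleotide chip by a Toray protocol, per the labels' protocols. There were 2 arrays, 1 per lobe. On each, saline RNA was in Cy5 and OBP-801 RNA in Cy3, per the labels. The deposited scanner files give the spot intensity and the local background intensity of each wavelength as medians, per the file headers, reconciled over 3 scanner gains by a least-squares fit whose coefficients stand in the header. These intensity values were not background-subtracted or normalized. The image analysis software was not given in the sources used here. The deposited value table holds log2 values whose making no header describes. Set against the scanner files, they equalled log2 of Cy3 over Cy5 after subtraction of the mean of the blank spots (5% left out at each end), less a constant of 1.08 (ventral) or 1.00 (lateral), with an SD of the remainder of 1.7e-05 and 2.1e-05. They are therefore log2 ratios of OBP-801 over saline, centred on a median of 0. Probes were listed (15699 and 14372) almost exactly where both channels exceeded the blank mean by 2 SD, with 9 and 8 exceptions.

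Ratios were computed from the scanner files with limma 3.58.1 in R 4.3.3. The spot medians were corrected with normexp and an offset of 50 without the local background, and log2 ratios were normalized within each array by loess with control spots given weight 0. The local background was left out because it rose with the spot itself (correlation of log2 values 0.915 to 0.987 across gene probes). Its use raised the SD of the log2 ratio over 24 spots of a positive control from 0.12 to 1.21 on the ventral array. Whether to use the local background had not been fixed beforehand. The choice was made after both forms had been run and their counts seen, 67 higher and 25 lower ventral probes and 59 and 59 lateral probes without it, against 456 and 19, and 276 and 36, with it. A channel was called well above background where the spot exceeded the mean of 5808 blank spots by 2 SD, with 5% of blanks left out at each end. That limit was 17.3 units (saline) and 62.9 units (OBP-801) on the ventral array and 16.6 and 69.7 units on the lateral array. Treatment comparisons used probes well above background in at least 1 channel. Net signals are spot medians less the blank mean. At the detector ceiling of 65535 units lay 1 probe in ventral and 2 in lateral OBP-801 RNA. The scanner flagged 5 and 8 gene probes at some gain, which were kept. Lobes were compared in the Cy5 signals after Aquantile normalization between arrays. The number of arrays limits the precision throughout.

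With 1 array per lobe no test across samples was made. Results are ratios, counts of probes at least 2-fold apart, and correlations across probes. Comparisons, thresholds and most alternatives were fixed before the data were examined. The form of the background, the alternative with the local background, the alternative limited to probes 10 blank SDs above the blanks, and the groups of probes set by enrichment came after. The planned subtraction of the median blank was made with the trimmed blank mean instead. The named genes were to be the most changed ones with a gene symbol, plus members of 43 gene lists and some single genes of interest. None of the 20174 probe IDs could be matched to a symbol in the files or in the reference gene table used here, so no list was evaluated. In their place the 2 probes with the largest increase and the 2 with the largest decrease common to both lobes, detected in all 4 channels, were named by ID. Every other probe described was chosen after its values were seen and is given without its ID.

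The ratio calculation was tested on simulated data, made from the real Cy5 signals of each array with 200 probes changed. Noise was that of the blanks and of the less variable positive control. The simulated dyes differed by a constant factor, without a dye preference of any probe or a trend with brightness. Of simulated 4-fold increases, 64% in the ventral and 72% in the lateral array were called at least 2-fold, and of 4-fold decreases 46.9% and 46%. Of simulated 3-fold increases 52% and 64% were called, and of 3-fold decreases 34% and 44%. Among unchanged probes 0 of 17443 and 0 of 15940 were called, a count that leaves out false calls from dye preference, dye trend or larger spot noise. With subtraction of the blank mean instead, 100% and 98% of the 4-fold increases were called, together with 5.93% and 5.66% of unchanged probes. Alternatives comprised other background corrections, no loess, other filters and thresholds, and the authors' log2 table. Summaries were made in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.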

Results

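Gene expression was measured in prostate cancer tissue of TRAP rats, a transgenic line in which the SV40 T antigen under a probasin promoter gives rise to prostate tumours. Rats were treated with OBP-801, an inhibitor of histone deacetylases (the enzymes that remove acetyl groups from histones and other proteins), or with saline. Treatment began at 6 weeks of age and consisted of 2 intravenous injections per week for 8 weeks. The dose was given per kilogram of body weight in the treatment protocol (1 mg/kg) and without a body weight elsewhere in the labels. RNA of the ventral prostate was compared on 1 two-colour array and RNA of the lateral prostate on another, with saline RNA in Cy5 and OBP-801 RNA in Cy3 on both. The number of rats behind each RNA was not stated in the sources used here. With 1 array per lobe there was no replicate, so no difference below carries a test across animals, and no array with the dyes exchanged was analysed, so the dye and the treatment cannot be told apart for any single probe. The only error that could be measured was technical. Over 24 replicate spots of each of the positive controls, the log2 ratio had an SD of 0.07 and 0.12 on the ventral array and of 0.06 and 0.08 on the lateral array. The means of these controls, which ran from -0.33 to 0.16, show that their ratios also departed from 0.

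Each array carried 20174 gene probes, and each probe was identified by an Ensembl rat gene ID. Neither the files nor the reference table used here pairs these IDs with gene symbols, so genes are given by ID, and only the 2 most increased and the 2 most decreased in both lobes are named. In the ventral prostate 16478 probes (81.7%) exceeded the detection limit set from the blank spots in saline RNA and 16375 (81.2%) in OBP-801 RNA. In the lateral prostate the numbers were 14837 (73.5%) in saline RNA and 15269 (75.7%) in OBP-801 RNA. Passing this limit, called detected here, is weak evidence of expression, since of 809 spots described as having no probe 61.9% (ventral) and 63.7% (lateral) also passed it in Cy5, and 27.9% and 29.4% in Cy3. A limit of 10 blank SDs in both channels was passed by 11830 ventral and 10803 lateral probes. A small set of transcripts gave much of the signal. The 100 brightest probes held 23.0% of the net signal in ventral saline RNA, 20.9% in ventral OBP-801 RNA, 24.6% in lateral saline RNA and 24.0% in lateral OBP-801 RNA. Of the 100 brightest probes in saline RNA, 81 were the same in both lobes, and the number was also 81 in OBP-801 RNA.

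The first comparison asked how OBP-801 altered expression in the ventral prostate. Of 17153 probes detected in at least 1 channel, 67 were at least 2-fold higher with OBP-801 and 25 were at least 2-fold lower. Together they made 0.536% of the probes. In the simulation of this array 4-fold decreases were called less often than 4-fold increases, 46.9% against 64%, so the processing may contribute to that balance. The log2 ratio of 95.9% of the probes lay within 1.5-fold of no change, and the middle 95% of the ratios ran from -0.50 to 0.59 on the log2 scale. Among probes detected in both channels, the 10 most increased ranged from 2.76-fold to 10.1-fold higher, and the 10 most decreased from 2.26-fold to 2.74-fold lower. The 10.1-fold probe had 8.30 net units in ventral saline RNA, and technical causes of its rise stay open, as described at the end. The higher probes were dimmer in saline RNA than the lower ones, with a median net signal of 228 units against 1074 units. Choosing probes by a ratio over the saline signal, with an offset added, favours this order in advance. For 2 of the 67 higher probes the saline signal was not well above background, so their fold is only a lower bound. The folds include an offset of 50 intensity units that pulls the ratios of dim probes towards 0, and the authors' deposited log2 values, made with neither the offset nor loess, gave 591 higher and 205 lower probes, of which 56.4% had a net signal below 10 blank SDs in at least 1 channel. The count and the balance of directions depend on the processing. Median centring instead of loess, with the offset kept, gave 599 higher and 2 lower, and subtraction of the local background gave 456 higher and 19 lower. The authors' values, also centred on a median without loess, had 205 lower. Leaving out loess therefore does not by itself account for the 2 lower probes.

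The same question was asked of the lateral prostate. Of 15726 detected probes, 59 were at least 2-fold higher with OBP-801 and 59 at least 2-fold lower, 0.75% of the probes together. Simulated 4-fold decreases were called less often than increases on this array as well, 46% against 72%. The 10 most increased probes detected in both channels ranged from 2.69-fold to 4.16-fold higher, and the 10 most decreased from 2.81-fold to 7.93-fold lower. The probe with the 7.93-fold decrease had a log2 ratio of 1.99 in the ventral prostate. As in the ventral lobe, the higher probes had the lower median net signal in saline RNA, 261 units against 741 units, an order that the choice by ratio favours here too. The ratios of 95.5% of the probes lay within 1.5-fold of no change, on the scale with the offset. The authors' deposited log2 values gave 459 higher and 276 lower probes, of which 53.7% had a net signal below 10 blank SDs in at least 1 channel. Here too the balance turned on the processing. Median centring with the offset kept gave 526 higher and 7 lower, and subtraction of the local background gave 276 higher and 36 lower. The authors' values, centred on a median with neither offset nor loess, had 276 lower.

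The response was then compared between the lobes over 15465 probes detected on both arrays. Of the 67 probes higher in the ventral and the 59 higher in the lateral prostate, 29 were shared, where independent lists of these sizes would share 0.26. Of the 25 and 59 lower probes, 14 were shared, against 0.0954 for independent lists. Under median centring instead of loess, with the offset kept, 365 higher and 0 lower probes were shared. The authors' values, with neither offset nor loess, gave 204 and 75. Of the 166 probes that changed at least 2-fold in either lobe, 159 (95.8%) had a ratio of the same sign in both, against 77.7% of all compared probes. Across probes, which are not independent replicates, the log2 ratios of the lobes correlated with a Pearson r of 0.827 and a Spearman rho of 0.800. The Pearson r was 0.499 with subtraction of the blank mean and 0.615 when the local background was subtracted. With subtraction of the blank mean, probes at least 10 blank SDs above the blanks in both channels had an r of 0.828. That limit was chosen after the data were seen. Both arrays had saline in the same dye, so a preference of a probe for either dye would enter both ratios in the same direction. Between the arrays, blank spots correlated with an r of 0.148 and spots described as having no probe with an r of 0.516.

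Among probes well above background in both channels of both arrays, ENSRNOG00000005743 had the largest increase common to both lobes. Its net signal was 222 units in saline and 2449 units in OBP-801 RNA of the ventral prostate, and 608 and 3957 units in the lateral prostate, which after normalization corresponded to 4.54-fold and 3.08-fold higher levels on a scale that includes the offset and loess, so they are not ratios of the net signals, which differ between the dyes. ENSRNOG00000015519 was 3.70-fold higher in the ventral and 2.81-fold higher in the lateral prostate. Of the probes that were lower in both lobes, ENSRNOG00000016460 was among the brighter probes, with 34542 units in ventral and 33174 units in lateral saline RNA, and its level with OBP-801 was 2.74-fold and 2.42-fold lower in these lobes. ENSRNOG00000008816 was 2.44-fold lower in the ventral and 3.13-fold lower in the lateral prostate, and in saline RNA its log2 signal was 2.03 higher in the ventral than in the lateral lobe. These log2 ratios ran from 1.49 to 2.18 for the increases and from -1.65 to -1.28 for the decreases. Without any normalization ENSRNOG00000008816 had a log2 ratio of -0.20 in the ventral and ENSRNOG00000016460 one of -0.11 in the lateral prostate, so the size of their decrease rests on the correction of the dye balance.

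**Figure D1:**
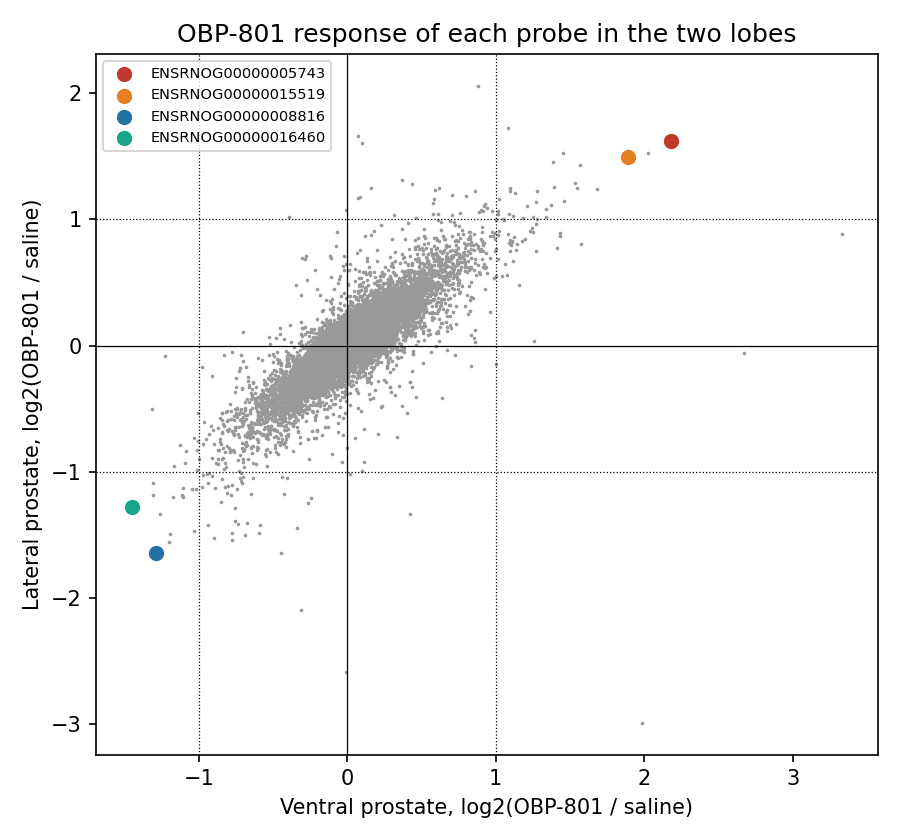
Each grey point is 1 of the 15465 probes detected on both arrays, with the log2 ratio of OBP-801 over saline in the ventral prostate on the x axis and in the lateral prostate on the y axis; dotted lines mark 2-fold and coloured points the 4 probes named by ID. The probes lie along the diagonal (Pearson r 0.827), with 29 beyond the dotted lines in the upper right and 14 in the lower left.

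The difference between the 2 ratios of a probe is less open to a dye preference that both arrays share, although the offset can shrink that preference unequally where a probe is dim in only 1 lobe. The difference was under 1.5-fold for 99.2% of the compared probes, with an SD of 0.16 on the log2 scale across probes. For dim probes the offset also pulls this difference towards 0, so that share does not measure how alike the lobes were. The ventral ratio was at least 2-fold above the lateral ratio for 15 probes, and the lateral ratio at least 2-fold above the ventral ratio for 9. The largest difference came from a single probe with a net signal in the ventral prostate of 32.8 units in saline and 529 units in OBP-801 RNA, while in the lateral prostate the signal was 2931 units in saline and 680 units in OBP-801 RNA. It is the probe that was 7.93-fold lower in the lateral prostate. The largest difference in the other direction came from a probe that had 15.6 units in lateral saline and 278 units in lateral OBP-801 RNA, against 2.32 and 10.4 units in the ventral lobe. The counts depend on the processing, and the authors' deposited log2 values gave 121 and 213 probes. Subtraction of the blank mean without an offset gave 473 and 487.

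The last comparison set the lobes against each other in saline-treated rats, in the Cy5 signals of the 2 arrays. Of 16613 probes detected in saline RNA of at least 1 lobe, 73 were at least 2-fold higher in the ventral and 91 in the lateral prostate. On this scale, where the offset draws dim probes together, 96.4% were within 1.5-fold. The 10 probes most enriched in the ventral lobe, among those detected in both, were 2.87-fold to 4.35-fold higher there. Enrichment in the lateral lobe reached further, with the 10 most enriched probes 4.70-fold to 315-fold higher, and 5 of the 91 lateral probes were not well above background in ventral saline RNA. The 315-fold probe is the one that was 10.1-fold higher with OBP-801 in the ventral prostate, with 8.30 net units in ventral saline RNA. With OBP-801 the lobes differed at least 2-fold for 156 probes in the ventral and 137 in the lateral direction. Of the 73 ventral probes 59 also passed in OBP-801 RNA, as did 76 of the 91 lateral probes. The log2 differences in saline and in OBP-801 RNA correlated with an r of 0.879 over 16013 probes, but both come from the same 2 arrays, so array and lobe cannot be told apart. Subtraction of the blank mean without an offset turned the balance, giving 2111 ventral and 263 lateral probes, and for probes at least 10 blank SDs above the blanks in both lobes it gave 565 and 113.

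**Figure D2:**
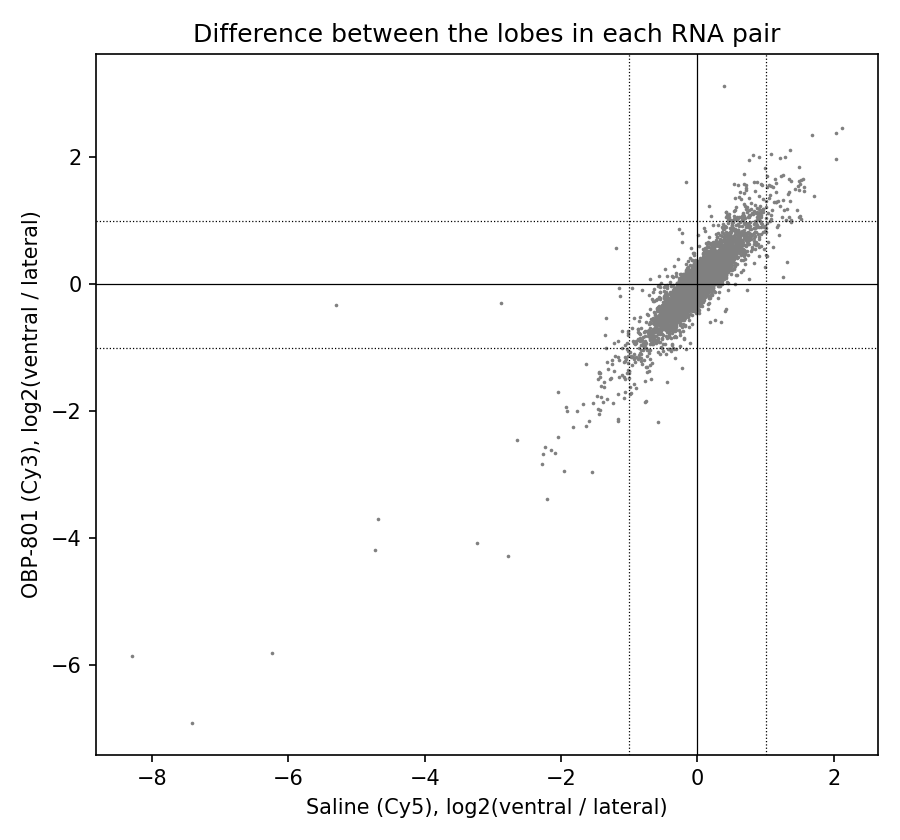
Each point is 1 of 16013 probes, with the log2 difference of ventral minus lateral signal in saline RNA (Cy5) on the x axis and in OBP-801 RNA (Cy3) on the y axis; dotted lines mark 2-fold. The points follow the diagonal (Pearson r 0.879), and the lateral side reaches further from 0 than the ventral side.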

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

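The comparison of control spots with blanks was chosen after the data were seen. A single probe, described above as the one with the largest difference between the lobes, moved at least 2-fold in opposite directions. Its log2 ratio of OBP-801 over saline was 1.99 in the ventral and -2.99 in the lateral prostate. The difference was not tested, since each lobe has 1 array. Its log2 difference of ventral minus lateral signal was -5.30 in saline RNA and -0.32 in OBP-801 RNA.

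Signal also appeared in spots outside the gene probes. Of 809 spots described as having no probe, 61.9% on the ventral and 63.7% on the lateral array exceeded the detection limit in Cy5, and 27.9% and 29.4% in Cy3, the same limit that the gene probes had to pass. Blank spots exceeded it in 8.97% and 9.62% of cases in Cy5 and 8.02% and 8.23% in Cy3. The excess was small in size, with a median Cy5 signal of 17.8 units against 15.6 in blanks on the ventral array. Of 521 quality control spots, 74.3% exceeded the limit in Cy5 and 73.9% in Cy3 on the ventral array, and 62.2% and 67.2% on the lateral array.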

How the results depend on the processing

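The alternatives with the local background and with a limit of 10 blank SDs were chosen after seeing the data. No paired analysis was possible because each lobe has 1 array. The gene list alternatives were not run, since no probe could be matched to a symbol, and the value table holds no lobe levels. In the order higher and lower in ventral, then higher and lower in lateral, the 2-fold counts of 67, 25, 59 and 59 became 962, 681, 801 and 631 with subtraction of the blank mean, 599, 2, 526 and 7 with median centring, 3443, 0, 2621 and 3 with no normalization, 591, 205, 459 and 276 in the authors' table, 432, 276, 388 and 312 at 1.5-fold, and 7, 0, 5 and 5 at 3-fold. Of the calls made with normexp and loess, 64 of 67, 25 of 25, 58 of 59 and 56 of 59 were also at least 2-fold in the authors' table. That table comes from the same spot intensities without the offset, which pulls ratios towards 0. This overlap was therefore largely set in advance. Shared higher and lower probes (29 and 14) became 300 and 127 with blank subtraction, 365 and 0 with median centring, 2332 and 0 with no normalization, 204 and 75 in the authors' table, 261 and 183 at 1.5-fold, and 1 and 0 at 3-fold. Probes with the higher ventral or the higher lateral ratio (15 and 9) became 473 and 487 with blank subtraction, 24 and 15 with no background correction, 121 and 213 in the authors' table, 67 and 50 at 1.5-fold, and 6 and 1 at 3-fold, and the lateral count became 18 with median centring and 16 with no normalization. Probes higher in ventral or lateral saline RNA (73 and 91) became 2111 and 263 with blank subtraction, 323 and 268 at 1.5-fold, and 5 and 27 at 3-fold. The same comparison in the Cy3 channel, which holds OBP-801 and not saline RNA, gave 156 and 137. The Pearson and Spearman correlations between lobes were 0.499 and 0.650 with blank subtraction, 0.807 and 0.787 with no background correction, 0.890 and 0.894 with median centring and with no normalization, 0.832 and 0.818 with both channels above background, 0.819 and 0.728 with no filter, and 0.716 and 0.723 in the authors' table. Normexp after subtracting the local background gave 456 higher in ventral, 276 higher and 36 lower in lateral, 129 and 8 shared, correlations of 0.615 and 0.571, 194 and 82 differing, and 346 and 536 between lobes in saline. Blank subtraction limited to probes at least 10 blank SDs above the blanks gave 266, 94, 202 and 143, then 110 and 32 shared. It also gave Pearson and Spearman correlations of 0.828 and 0.842, 35 and 21 differing, and 565 higher in ventral saline RNA. Of 134 values under an alternative, with the Cy3 comparison included, 43 stayed within 1.5 times or within the interval of the correlation and 91 did not. That interval comes from the Pearson correlation, takes probes as independent and is narrow. The correlations cannot move with the fold threshold, so this split is not a measure of stability. The balance of directions turned over between lobes in saline RNA with blank subtraction, with and without the limit of 10 blank SDs, and at 1.5-fold. It also turned over between the ratios of the lobes with blank subtraction and in the authors' table. In the Cy3 channel the balance between lobes was also the other way, but that is a comparison of other RNA. The 4 probes named by ID kept their direction in all 56 values under other background corrections and normalizations. Their values under the limit of 10 blank SDs repeat those of blank subtraction. The probes had been picked as the most changed in both lobes, which favours a stable direction. Fewer calls at 3-fold follow from the threshold itself. For blank subtraction the simulation showed 5.93% and 5.66% of unchanged probes past 2-fold. For the remaining changes the cause was not tested. Median centring and no normalization both kept the offset of 50, which the authors' values do not have. A signal over 10 blank SDs in both channels was reached by 11830 ventral and 10803 lateral probes.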

Other observations

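The tests of a dye trend with brightness, of position on the chip, of a mixture of lateral RNA and of a smaller share of ventral tissue were chosen only after the result was seen, as were the probe groups they use. The transcripts that distinguish the lobes in saline RNA differed in their ratios. Of the 91 probes at least 2-fold higher in lateral than ventral saline RNA, 78 had a ratio above 0 in the lateral prostate with OBP-801, with a median log2 ratio of 0.57 (1.05 under median centring instead of loess), and 14 were at least 2-fold higher and 3 at least 2-fold lower. The same probes had a median of 0.30 in the ventral prostate (0.60 with blank subtraction and 0.56 under median centring), with 76 above 0, 9 at least 2-fold higher and 0 lower. Of the 73 probes enriched in the ventral lobe, 58 had a ratio below 0 in the lateral prostate, with a median of -0.31 (-0.54 with blank subtraction, -0.53 in the authors' values, -0.04 under median centring and 0.35, the other direction, with no normalization). In the ventral prostate 54 of them were below 0, with a median of -0.37, which was -0.43 with blank subtraction and in the authors' values. It turned to 0.19 under median centring and 0.63 with no normalization, both with the offset kept and no loess. Leaving out normalization moves every probe of an array by the same amount from its median-centred value, so that shift is not particular to these probes. Each median after loess lay outside the medians of 10000 random probe lists matched on brightness, whose middle 95% ran from -0.06 to 0.09 for the lateral-enriched probes in the lateral prostate. The random lists were not picked by their saline signal. In the ventral prostate, where that choice favours the direction seen, the comparison cannot set it apart from a response. These places among random lists describe these arrays and not other rats.

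A candidate explanation is the choice of probes, because enrichment and response share the saline channel. In the lateral prostate that sharing pushes lateral-enriched probes down and ventral-enriched probes up, against their medians of 0.57 and -0.31, while in the ventral prostate it acts in the direction observed and may contribute. A smaller share of ventral tissue in the lateral OBP-801 RNA would raise strongly lateral probes by about a single factor. Of 27 probes at least 3-fold enriched, 44.4% lay within 0.32 of their median on the log2 scale. The exact 95% interval, which takes probes as independent, was 25.5% to 64.7%. The interval excludes the 80% set for a single factor but not the 50% set against it, a reading of the interval adopted after the value was seen. Probes of 1 array are not independent replicates, however, and the ratios of all lateral probes had an SD of 0.27. A single factor need not hold 80% of the probes that close to their median. The test therefore cannot decide on that share as the whole cause, and a partial contribution stays open. Of the 27 ratios, 22 were above 0 and 5 below 0. A response of lobe-enriched transcripts to OBP-801 stays open as a hypothesis, untested with 1 array per lobe. For the ventral-enriched probes its direction in the ventral prostate and its size in the lateral prostate depend on the processing.

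The correlation of the ratios between the lobes has technical and biological readings. A dye trend with brightness as the whole cause is argued against by the Pearson r of 0.827 that remained after loess (0.890 under median centring). After loess the r was 0.499 with blank subtraction and 0.615 with the local background. It was 0.828 with blank subtraction limited to probes over 10 blank SDs. Position on the chip, as far as touching spots share it, is argued against by the r of 0.0528 (ventral) and 0.0406 (lateral) between the ratio of a probe and the median ratio of the detected gene probes touching it. Spots described as having no probe correlated with an r of 0.516, so correlation between the arrays is not limited to gene probes. The dye preference of each probe and a shared response to OBP-801 cannot be told apart, since 0 arrays had the dyes swapped. Other differences between the saline and the OBP-801 rats, whose number was not stated, could also enter the ratios of both lobes. These arrays cannot separate them from the treatment either.

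Of 7 probes at least 8-fold brighter in lateral than ventral saline RNA and at least 500 units there, 5 were at least 2-fold higher in the ventral prostate with OBP-801, a direction that picking probes by a low ventral saline signal also favours. The brightest rose from 8.30 to 1032 net units in the ventral prostate, against 15715 and 65471 units in the lateral prostate, where the OBP-801 spot was saturated. Lateral RNA mixed into the ventral OBP-801 RNA may contribute, but the ventral Cy3 signal beyond that of saline RNA was 3.62%, 0.561%, 3.40%, 1.19%, 67.8% and 0.263% of the lateral Cy3 signal for the 6 probes not saturated, with 50% of them within 3-fold of the median (100% of the 2 at background in ventral saline RNA, too few to decide). Even with all of their ventral Cy3 signal taken as mixed RNA the other probes allow a share of at most 0.565%. This limit is set by 1 probe at background in ventral saline RNA, and the other such probe allows 1.19%. It takes the net signals of the 2 arrays as comparable and any mixed RNA as like the lateral RNA measured. The share of 0.565% supplies 0.833% of the gain of the probe with a log2 ratio of -2.99 in the lateral lobe. For the probes at 3.62% and 3.40% it supplies 15.6% and 16.6%. Under these assumptions mixing is argued against for the first and as the whole cause for the other 2. It stays open for the 2 at background, where the share supplies 101% (the probe that set it) and 47.5%, and for the saturated probe (36.4%). Spill from bright neighbouring spots also stays open, with a median of 5.20 for the brightest touching spot over the probe itself, though for the saturated probe it was 1.17, as does a rise of these transcripts in the treated ventral lobe, which was not tested.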
